A study of Arabidopsis thaliana with 4 samples.

How the data were processed

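Transcript levels were measured in whole 9-day-old Arabidopsis thaliana seedlings of the wild type (Columbia) and of the css1 mutant. Each genotype had 2 independent biological RNA samples, each hybridised to its own 1-colour Affymetrix array, so 4 arrays were used and no column was left out. Per the labels' protocols, seedlings grew under continuous light on agar with 2% sucrose, and biotin-labelled cRNA was made from 250 ng of total RNA. The deposited values are log2 signals for 22810 probe sets, computed by the authors with RMA per the submitters' processing notes. The version of RMA is not stated, and detection calls and scanner software are not given in the sources used here. No further logarithm, background step or scaling was applied. Array medians lay between 6.32 and 6.37 on the log2 scale. The values carry no counts, so the number of arrays limits the precision: the median standard error of a css1 to wild-type difference was 0.10 log2 units.

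The 64 Affymetrix control probe sets were set aside, leaving 22746 probe sets for the tests. The probe annotation supplied with the series gave 1 gene for 13513 probe sets and several genes for 503, and it did not list 8730. Probe sets were joined to loci by gene ID, which matched 13436 of the 13513, and 77 were not matched in this way. Of the probe sets with 1 gene, 283 carry a suffix that marks probes shared between transcripts. The 13355 named loci included 147 with several probe sets, and each of these was represented by the probe set with the highest mean over the 4 arrays. The unlisted probe sets were tested and counted, but their genes are not named here. Genes of the mitochondrial and plastid genomes were matched by symbol and gene ID instead of the locus prefix set out in the plan, since the annotation gives them no such prefix. No coordinates are given.

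Genes were compared between css1 and wild type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term, two-sided). A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over all 22746 probe sets. Errors are given as the standard deviation of the 2 arrays of a genotype or as the standard error from limma, and folds are 2 to the power of the difference in mean log2 value. The groups, gene lists, tests, alternatives and the rule for naming genes were set before the data were examined. The rule named the 10 loci with the largest rise and the 10 with the largest fall among probe sets with 1 locus that passed and whose css1 values both lay on the same side of both wild-type values. It also named up to 4 members of each gene list with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen.

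Of 33 fixed gene lists, 22 had at least 3 measured members and were tested as sets. The minimum of 3 was set after the coverage was known. The lists other than the organelle genomes held 507 members, of which 128 were measured by a named probe set. Another 2 members were dropped since their symbols contradicted the reference. Coverage was 3 of 14 members for cellulose synthesis, 3 of 17 for starch synthesis, 3 of 21 for sucrose, 6 of 20 for anthocyanin and 8 of 44 for nuclear photosynthesis. A list result holds for the measured members only. The lists for phosphate starvation, nitrate and seed storage had no measured member and are not analysed here. List shifts were tested with limma's camera against all other loci at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists. Counts of list members are given at the threshold over all probe sets and adjusted over the list alone. The lists covered mitochondrial function, carbon metabolism and cell walls, since a mutant of this name has been described as affected in these, along with stress, hormone, nutrient and tissue markers. The labels do not state which gene is affected in css1, and its transcript is not analysed here.

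The alternatives for single genes were a filter at the 30th percentile of mean signal, 1 probe set per locus, eBayes with trend or robust, median centring of each array, a second quantile normalization, array weights, the replicate number as a block, an adjusted p under 0.01, a fold of at least 2, a plain two-sample t-test and leaving out each array. With 1 array left out, the lone array of a genotype was assumed to vary like the other genotype. Without a css1 array, the spread thus came from the wild-type arrays alone, which varied more (median SD 0.086 against 0.067 in css1). Calls could then be lost at a nearly unchanged difference. The alternatives for lists were camera with an estimated correlation, limma's fry, the filter, centring, the replicate block, the mean of all probe sets of a locus and leaving out each array. With 2 arrays per group, no other split of the arrays could serve as a reference and no outlier test was made.

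The procedure was tested on simulated data with known changes. Random lists matched on mean expression, 4 further gene lists, the control probe sets and 43 families of genes with a shared symbol were examined after the first results. The genes of the further lists were written down before their values were seen. The array reports transcript abundance only, so splicing, proteins, metabolites and growth are not analysed here.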

Results

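Whole 9-day-old seedlings of the wild type and of the css1 mutant were compared on 2 arrays per genotype, each from an independent RNA sample. Each array gave log2 signals for 22746 probe sets after the controls were set aside, and the number of arrays limits the precision. The correlation across probe sets was 0.996 between the wild-type arrays, 0.997 between the css1 arrays and 0.982 to 0.986 between genotypes. The first principal component separated the genotypes and held 80.2% of the variance, and the second held 12.1%.

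By camera at its preset correlation, lists of mitochondrial stress, respiration, starch synthesis and anthocyanin genes were higher in css1, and those of hypoxia, sugar-starvation and plastid-encoded genes lower. None of these list calls passed with an estimated correlation. That estimate was below the preset 0.01 for the mitochondrial stress (−0.003), anthocyanin (−0.007), starch synthesis (−0.05) and alternative respiration (−0.13) lists. For the other lists called it was above the preset, from 0.05 for complexes II to V to 0.82 for the tricarboxylic acid cycle. Correlated members therefore do not account for the loss in the lists with the lower estimate. With an estimated correlation, camera rests on the 2 residual degrees of freedom of the fit, which raises p. For the mitochondrial stress list, the unadjusted camera p went from 3.13e-14 to 0.0150. A list call lost with this setting is thus not by itself a sign of correlated members. Among the named genes, the largest log2 rises were in genes for a chitinase, a lipase and a lipid transfer-type protein, and the largest falls in genes for a glycine-rich protein and a methyltransferase-type protein, with the signal of the lipase near the floor of the arrays in wild type. Of the 22 lists tested as sets, anthocyanin synthesis had the highest median, followed by mitochondrial dysfunction. Only 3 of 14 members for cellulose synthesis, with no cellulose synthase, and 3 of 4 nuclear maturases were measured, and these lists showed no shift.

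Transcripts of AT2G43620, a gene of the chitinase family, rose 22.9-fold, from a log2 signal of 6.99 ± 0.29 (SD, n = 2) in wild type to 11.51 ± 0.20 (SD, n = 2) in css1 (limma, Benjamini-Hochberg adjusted p = 5.90e-04). AT1G54020, a GDSL-type lipase gene, rose from 3.32 ± 0.02 (SD, n = 2) to 7.43 ± 0.35 (SD, n = 2) (log2 difference 4.11, adjusted p = 7.29e-04), and AT4G22470, which encodes a lipid transfer-type protein, rose from 5.23 ± 0.58 (SD, n = 2) to 9.22 ± 0.03 (SD, n = 2) (adjusted p = 0.00168). UPOX (AT2G21640), a marker of mitochondrial oxidative stress, rose 13.8-fold (3.78, adjusted p = 8.54e-04), and the jasmonate-regulated oxygenase gene JRG21 rose from a low signal of 3.79 ± 0.08 (SD, n = 2) to 7.53 ± 0.68 (SD, n = 2) (3.74, adjusted p = 0.00278). The defensin gene PDF1.2, a marker of jasmonate and ethylene signalling, rose 12.8-fold (3.68, adjusted p = 0.00771), a call that was lost without css1 replicate 2 (3.45, adjusted p = 0.0626). LCR67, for a defensin-type cysteine-rich peptide, rose from 3.39 ± 0.06 (SD, n = 2) to 6.95 ± 0.82 (SD, n = 2) (3.57, adjusted p = 0.00481). The wild-type signals of AT1G54020 and LCR67 were near the floor of the arrays, so no fold is given for them and the size of their rises is uncertain. AT4G23680, for a major latex-type protein, rose 12.6-fold (3.66, adjusted p = 3.51e-04), and AT1G65500, for a small protein of unknown function, rose 11.8-fold (3.56, adjusted p = 8.54e-04). DFR, for the dihydroflavonol reductase of anthocyanin synthesis, rose 10.9-fold (3.44, adjusted p = 3.51e-04).

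The largest fall among the named genes was that of AT2G05540, for a glycine-rich protein, whose log2 difference was −3.38, a 10.4-fold fall (adjusted p = 4.63e-04). AT2G32160, for a methyltransferase-type protein, fell 8.13-fold (−3.02, adjusted p = 8.70e-04). AT5G59670, a leucine-rich repeat receptor kinase gene, fell from 6.23 ± 0.72 (SD, n = 2) to 3.39 ± 0.28 (SD, n = 2) (−2.84, adjusted p = 0.00686), a css1 signal near the floor, and this call was lost without css1 replicate 1 (−2.64, adjusted p = 0.0518). AT4G27450, a hypoxia-responsive gene, fell 4.28-fold (−2.10, adjusted p = 0.00581). AT5G52760, for a heavy metal-binding type protein, differed by −2.34 (adjusted p = 0.00517). AT5G10040 (−2.38, adjusted p = 0.00938), AT3G48640 (−2.33, adjusted p = 0.00155) and AT1G19530 (−2.16, adjusted p = 8.82e-04), for proteins of unknown function, fell as well. AT2G17850, for a rhodanese-type protein, differed by −2.22 (adjusted p = 0.00335) and AT1G64590, for a dehydrogenase-type protein, by −2.17 (adjusted p = 8.54e-04). Of these 20 genes, 18 passed without each array in turn. The rule required both css1 values of these genes to lie on the same side of both wild-type values. This also held for the 41 other genes that passed among those named from the lists below. Passing with 2 arrays per genotype largely brings this about, so it is no added support.

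In all, 3559 of 22746 probe sets (15.6%) passed, with 1736 higher and 1823 lower in css1, and 7214 had an unadjusted p under 0.05. With each array centred on its median, 2069 were higher and 1497 lower, so which direction held more calls depended on the scaling. At least 2-fold changes made up 569 of the calls (359 higher, 210 lower), and changes of at least 4-fold 88 higher and 18 lower. The median absolute log2 difference of the called probe sets was 0.60, and that of all probe sets together, with sign, was −0.03. The css1 values lay wholly above or below the wild-type values for 13655 probe sets (60.0%), where chance gives 33.3%. The calls included 1855 probe sets with 1 named gene, 85 with several and 1619 that the annotation does not list. The number of calls was 659 without css1 replicate 1, 560 without css1 replicate 2, 2227 without wild type replicate 2 and 3079 without wild type replicate 1. A two-sample comparison on the spread of each probe set alone, in place of limma's pooled spread, called 0 probe sets, with 4805 at an unadjusted p under 0.05. It rests on 2 degrees of freedom per probe set, so passing over 22746 probe sets was nearly out of reach. Its lack of calls therefore says little about single genes.

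**Figure D1:**
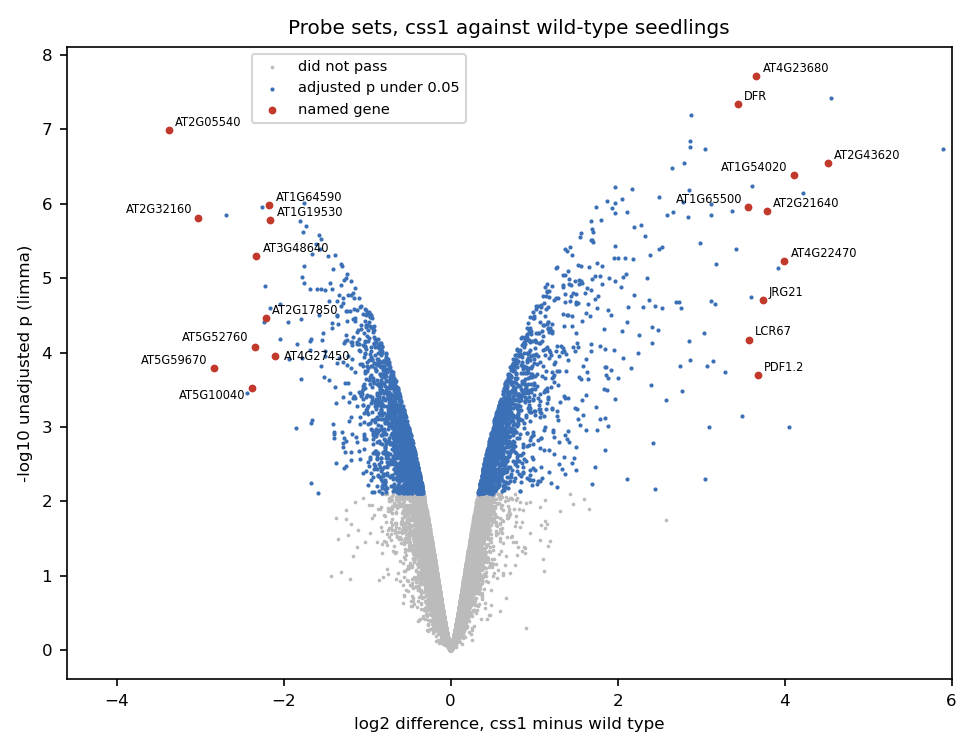
Log2 difference between css1 and wild type against the limma p for each probe set, with those past the adjusted threshold in blue. The 20 genes named by the rule are in red.

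Genes of the mitochondrial dysfunction response, which are induced when respiration is impaired, rose in css1. The list had a median log2 difference of 1.23 (camera adjusted p = 6.89e-13; adjusted p = 0.280 with an estimated correlation), and 13 of its 14 measured members rose, as did 13 adjusted over the list alone. AT12CYS-2, a stress marker with a twin cysteine motif, rose from 5.86 ± 0.05 (SD, n = 2) to 8.72 ± 0.13 (SD, n = 2) (2.87, adjusted p = 4.69e-04). HSP23.5, a mitochondrial small heat shock protein gene, rose by 2.78 (adjusted p = 8.54e-04), and AT1G24095, for a thiol-disulfide oxidoreductase-type protein, by 1.43 (adjusted p = 0.00137). UPOX, given above, also belongs to this list. Outside the rule, and chosen after their values were seen, the glutathione transferase gene GSTU25 rose by 2.42 and the methyltransferase-type gene AT2G41380 by 1.49. The remaining member, AT5G40690, a gene of uncertain function also outside the rule, was at −0.07. Without css1 replicate 1 or css1 replicate 2, 9 members passed.

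The bypass dehydrogenases of the respiratory chain rose in part. The list of alternative oxidases, type II NAD(P)H dehydrogenases and uncoupling proteins had a median of 0.25 (camera adjusted p = 0.00591; adjusted p = 0.338 with an estimated correlation), with 2 of 5 measured members called and 3 adjusted over the list alone. The type II dehydrogenase genes NDB4 (1.07, adjusted p = 0.00319) and NDB2 (1.02, adjusted p = 0.00567), the latter also in the dysfunction list, rose. NDB3 (0.25, adjusted p = 0.102) and NDB1 (0.21, adjusted p = 0.213) of the same family did not pass. The alternative oxidase genes of the list are not analysed here, since no probe set was named for them.

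The list of nuclear genes of complexes II to V and cytochrome c, with 12 of 22 members measured, was higher. Its median was 0.47 (camera adjusted p = 3.75e-07, and adjusted p = 0.280 with an estimated correlation). The members named here by the rule belong to complexes II and III and cytochrome c, so they cannot tell whether genes of complexes IV or V rose. The other members called are not assigned to a complex here. The calls were 8 of 12 members, and 10 adjusted over the list alone. CYTC-2, a cytochrome c gene, rose by 1.19 (SE 0.13, adjusted p = 0.00553). The succinate dehydrogenase genes SDH1-1 (0.85, adjusted p = 0.00973) and SDH2-2 (0.58, adjusted p = 0.0119) and the cytochrome c1 gene AT3G27240 (0.60, adjusted p = 0.0161) rose as well. Those 3 calls were lost without css1 replicate 1 and without css1 replicate 2, although the differences changed little. They were 0.89, 0.58 and 0.55 without css1 replicate 1, and 0.82, 0.58 and 0.65 without css1 replicate 2. The count was 1 without either of these arrays, 4 without wild type replicate 2 and 7 without wild type replicate 1.

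The list of nuclear complex I genes was higher, with a median of 0.26 (camera adjusted p = 1.82e-04; adjusted p = 0.544 with an estimated correlation), although 0 of 14 members passed limma's threshold over all probe sets. At an unadjusted p under 0.05 there were 8, all higher, and 6 rose adjusted over the list alone. With the filter, trend or centring 3 members passed, and with a second quantile normalization 1. The members with the smallest p were GLDH, for the enzyme of the last step of ascorbate synthesis (0.33, adjusted p = 0.0546), and the subunit genes AT1G67350 (0.36, adjusted p = 0.0568), AT3G08610 (0.30, adjusted p = 0.0673) and AT3G12260 (0.33, adjusted p = 0.0714). With fry in place of camera, the list's adjusted p was 0.0784. The median of the Bacillus poly-A control probe sets was 0.23. In size this was about as large as the median of this list, of the alternative respiration list (0.25) and of the tricarboxylic acid cycle list (0.28). These controls also varied between the wild-type arrays, as given with the control probe sets below.

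Genes of pyruvate dehydrogenase and the tricarboxylic acid cycle had a median of 0.28 (camera adjusted p = 8.29e-04; adjusted p = 0.604 with an estimated correlation; fry adjusted p = 0.157). The 2 of 8 members that rose, also 2 adjusted over the list alone, were the 2-oxoglutarate dehydrogenase gene AT3G55410 (0.62, adjusted p = 0.0132) and the succinate-CoA ligase gene AT5G23250 (0.60, adjusted p = 0.0206). Both were lost without css1 replicate 1 (adjusted p = 0.0940 and 0.104) and without css1 replicate 2 (adjusted p = 0.0924 and 0.141), and AT5G23250 also without wild type replicate 2 (adjusted p = 0.0535). The members AT5G65750, for another 2-oxoglutarate dehydrogenase (0.29, adjusted p = 0.0878), and AT5G08300, for another succinate-CoA ligase (0.34, adjusted p = 0.101), did not pass.

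**Figure D2:**
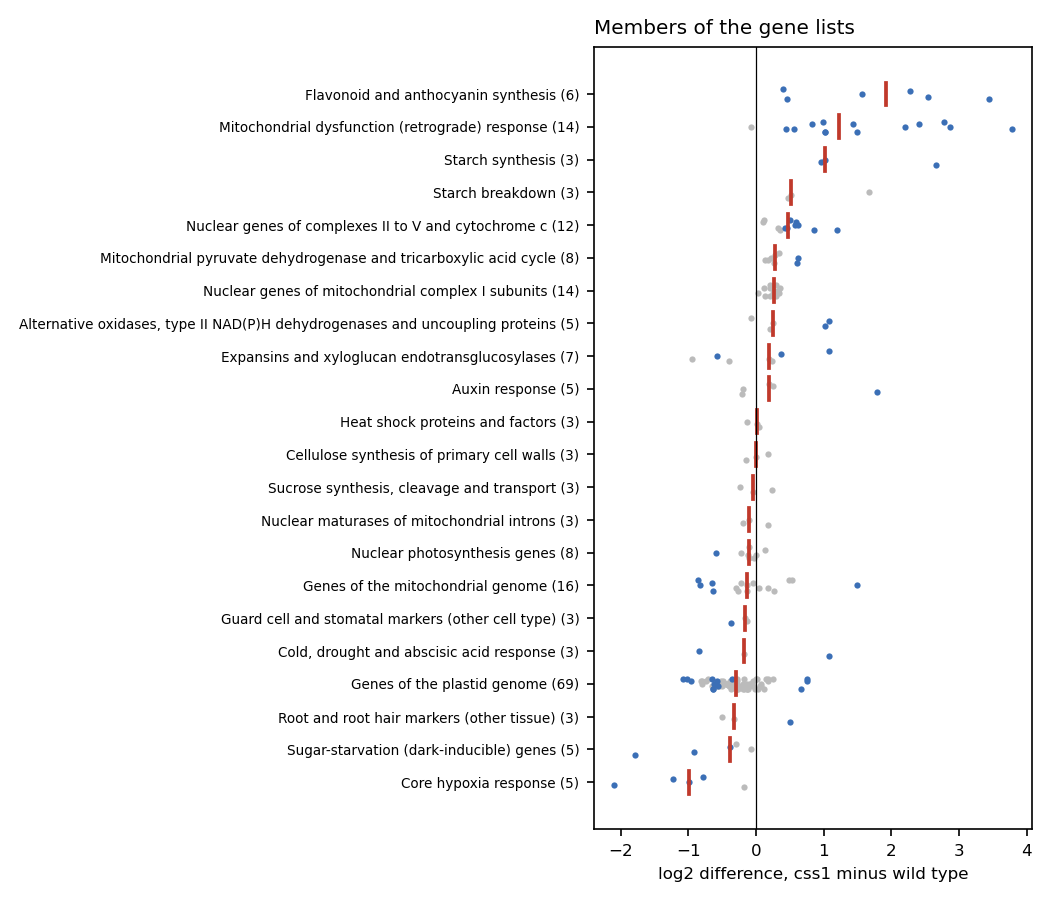
Log2 differences of the measured members of each gene list, with called members in blue, others in grey and the list median as a red bar. The number of measured members is in brackets.

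Starch synthesis genes rose, with a list median of 1.01 (camera adjusted p = 1.38e-04; adjusted p = 0.280 with an estimated correlation) and all 3 measured members called, as they were adjusted over the list alone. APL3, for a large subunit of the enzyme that makes ADP-glucose, rose from 6.05 ± 0.09 (SD, n = 2) to 8.70 ± 0.12 (SD, n = 2) (2.66, adjusted p = 6.20e-04). SBE2.2, for a starch branching enzyme, rose by 1.01 (adjusted p = 0.00529), and APL4, for another such large subunit, by 0.96 from a low wild-type signal of 3.64 (adjusted p = 0.0130). The call of APL4 was lost without css1 replicate 1 (adjusted p = 0.0840) and css1 replicate 2 (adjusted p = 0.0641), which left 2 of 3.

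The starch breakdown list did not pass, with a median of 0.52 (camera adjusted p = 0.0598) and 0 of 3 members called by limma, 2 at an unadjusted p under 0.05 and 1 adjusted over the list alone. It passed without wild type replicate 1 (0.93, adjusted p = 0.00390) and without css1 replicate 1 (0.56, adjusted p = 0.0177), with adjusted p from 0.00390 to 0.604 over all alternatives. The amylase gene AMY1 had a difference of 1.66 (SE 0.47, adjusted p = 0.0658) and passed without css1 replicate 1 (2.33, adjusted p = 0.0471; 0.0471 to 0.386 over all alternatives). The glucan water dikinase-type gene PWD (0.47, adjusted p = 0.137) and the disproportionating enzyme gene DPE1 (0.52, adjusted p = 0.234) passed without wild type replicate 1 (0.72, adjusted p = 0.0300, and 0.93, adjusted p = 0.0124), with ranges of 0.0300 to 0.449 and 0.0124 to 0.552 over all alternatives.

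Flavonoid and anthocyanin genes rose, with a list median of 1.92, the highest of the 22 lists tested as sets (camera adjusted p = 4.72e-08; adjusted p = 0.280 with an estimated correlation). All 6 measured members passed, as did 6 adjusted over the list alone, and 4 passed without each array in turn. Besides DFR, given above, the anthocyanin glucosyltransferase gene AT4G14090 rose by 2.28 (adjusted p = 9.79e-04), the flavonoid glucoside transferase gene UF3GT by 2.54 (adjusted p = 0.00137) and the anthocyanin malonyltransferase gene AT5MAT by 1.56 (adjusted p = 0.00223). The flavonol glycosyltransferase genes UGT78D1 and UGT78D2, chosen after their values were seen, rose by 0.46 and 0.40.

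The sucrose list showed no shift, with a median of −0.04 (camera adjusted p = 0.978) and 0 of 3 members called by limma or adjusted over the list alone, with 2 at an unadjusted p under 0.05. Its measured members were the sucrose exporter gene SWEET11 (−0.24, adjusted p = 0.119), the vacuolar invertase gene AT1G62660 (0.24, adjusted p = 0.146) and the sucrose phosphate synthase gene ATSPS4F (−0.04, adjusted p = 0.817).

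Genes induced by sugar starvation were lower, with a median of −0.38 (camera adjusted p = 0.00424; adjusted p = 0.516 with an estimated correlation; fry adjusted p = 0.0663). Of 5 members, 3 fell, and 4 adjusted over the list alone. AT3G15450, a sugar-repressed gene, fell by 1.79 (adjusted p = 0.00818), and AKINBETA1, for a subunit of the SnRK1 kinase, by 0.92 (adjusted p = 0.0114). Both were lost without css1 replicate 1 (adjusted p = 0.0576 for each) and css1 replicate 2 (adjusted p = 0.0639 and 0.0891), where 0 members passed limma's threshold and 2 and 3 had an unadjusted p under 0.05. IVD, a branched-chain amino acid breakdown gene, fell by 0.38 (adjusted p = 0.0443), a call lost without each array (adjusted p = 0.0792 to 0.230) and with centring (adjusted p = 0.0589). MCCA, of the same pathway, was at −0.29 (adjusted p = 0.101).

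Hypoxia genes were lower, with a median of −0.99 (camera adjusted p = 1.83e-04; adjusted p = 0.319 with an estimated correlation). Of 5 members, 4 fell, as did 4 adjusted over the list alone. AT3G10040, for the low-oxygen repressor HRA1, fell from 6.31 ± 0.13 (SD, n = 2) to 5.32 ± 0.01 (SD, n = 2) (adjusted p = 0.00486), and AT4G27450, given above, from 11.59 ± 0.50 (SD, n = 2) to 9.49 ± 0.08 (SD, n = 2). The wound-responsive gene AT4G10270 fell by 1.22 (adjusted p = 0.00867) and the kelch repeat gene AT3G27220 by 0.79 (adjusted p = 0.0110). The call of AT3G27220 was lost without css1 replicate 1 (adjusted p = 0.0755) and css1 replicate 2 (adjusted p = 0.0546), which left 3 of 5. The remaining member, the lactate dehydrogenase gene AT4G17260, outside the rule, was at −0.18 (adjusted p = 0.327).

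**Figure D3:**
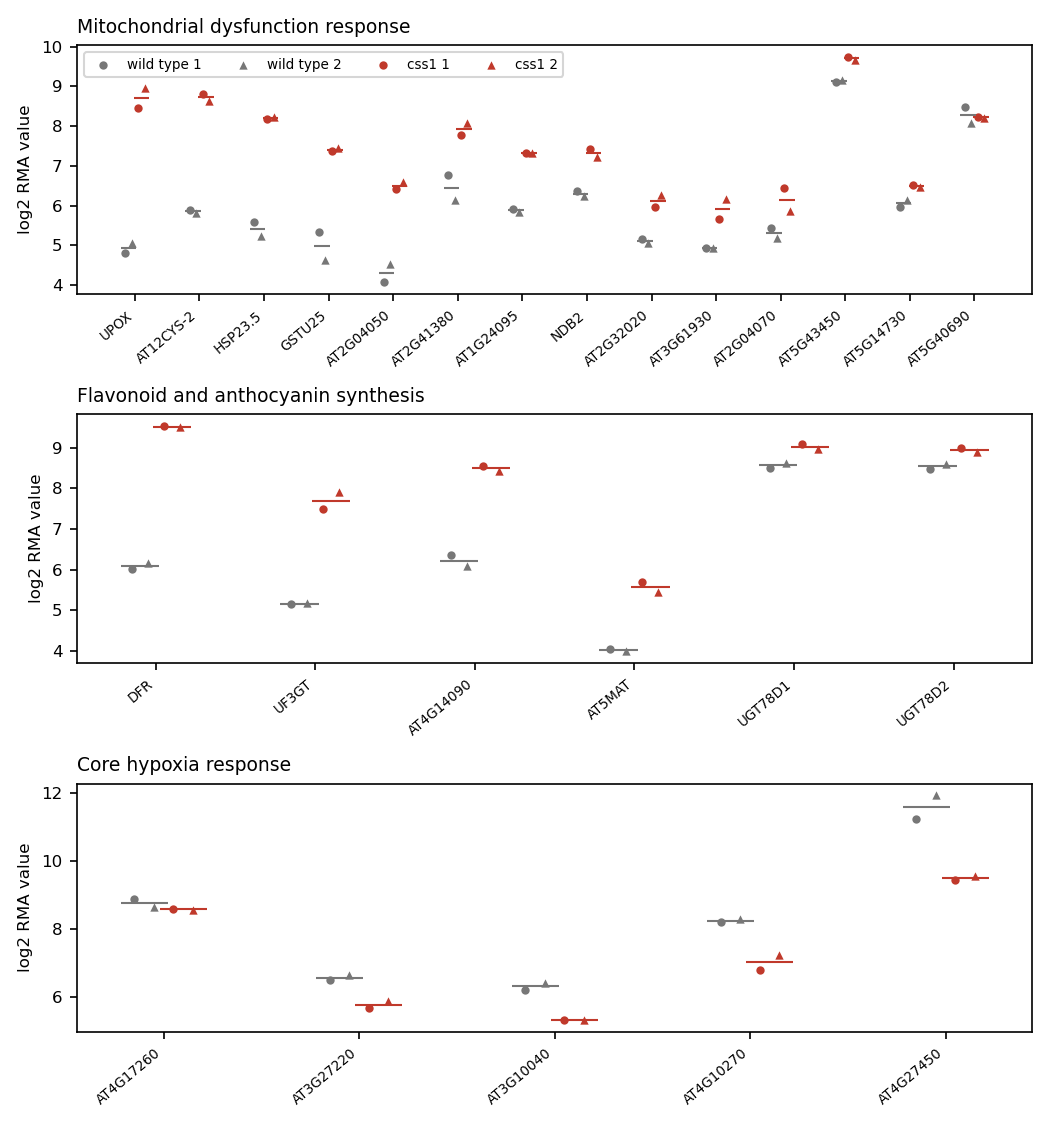
Log2 signals of the measured members of 3 lists on each array, with wild type in grey and css1 in red. Circles are replicate 1, triangles replicate 2 and lines group means.

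Signals for genes of the plastid genome were lower as a list, with a median of −0.30 (camera adjusted p = 1.83e-04; adjusted p = 0.544 with an estimated correlation; fry adjusted p = 0.276), and 56 of 69 genes had lower means. The median was −0.43 without css1 replicate 1 (camera adjusted p = 9.28e-08) and −0.16 without css1 replicate 2 (camera adjusted p = 0.0117). The calls were 11 lower and 3 higher, the same numbers adjusted over the list alone. The photosystem gene psbI rose by 0.75 (adjusted p = 0.00616), while the plastid dehydrogenase gene ndhK fell by 1.02 (adjusted p = 0.00811) and the photosystem genes psbA by 0.64 and psbF by 0.56 (adjusted p = 0.0127 each). Outside the rule, psbK of photosystem II and atpA of the plastid ATP synthase rose by 0.75 and 0.66. The calls of psbI, psbA and psbF were lost without css1 replicate 1 (adjusted p = 0.0528, 0.0784 and 0.0928) and css1 replicate 2 (adjusted p = 0.0641, 0.104 and 0.0986), and that of ndhK without css1 replicate 2 (adjusted p = 0.0687). The limma calls of lower genes numbered 5 without css1 replicate 1 and 0 without css1 replicate 2, where 15 were lower at an unadjusted p under 0.05. Those of higher genes numbered 0 without css1 replicate 1 or 2 (3 and 4 unadjusted) and 1 without either wild-type array.

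Genes of the mitochondrial genome did not shift as a list, with a median of −0.13 over 16 genes (camera adjusted p = 0.417). They had 1 higher and 4 lower calls, and 3 higher and 4 lower adjusted over the list alone. Of the 4 measured cytochrome c maturation genes, ccb382 was higher, from 7.54 ± 0.16 (SD, n = 2) to 9.04 ± 0.14 (SD, n = 2) (adjusted p = 0.00281), and ccb452 was lower by 0.65 (adjusted p = 0.0102), while ccb203 (−0.13, adjusted p = 0.452) and ccb206 (0.04, adjusted p = 0.802), outside the rule, did not pass. The complex I genes nad4L and nad9 fell by 0.64 (adjusted p = 0.0161) and 0.85 (adjusted p = 0.0171). Of the 16 genes, 9 lay above the filter's 30th percentile of mean signal, and nad9 was not among them. The complex I gene nad1, outside the rule, was lower by 0.84 (adjusted p = 0.0183) on its probe set with the highest mean, but its 7 probe sets ranged from −0.94 to −0.07 and 3 of them passed. The complex I gene nad4 and the cytochrome oxidase gene cox1, also outside the rule, were higher by 0.53 and 0.49. They did not pass limma's threshold over all probe sets (adjusted p = 0.0638 and 0.0808) but rose adjusted over the list alone. The measured complex I genes thus did not all move down. The calls of ccb452, nad4L and nad9 were lost without css1 replicate 1 (adjusted p = 0.0751, 0.0899 and 0.102) and css1 replicate 2 (adjusted p = 0.0862, 0.119 and 0.0687), where the lower calls by limma numbered 1 and 0, with 4 and 5 at an unadjusted p under 0.05. Organelle RNA is mostly not polyadenylated and has close nuclear copies in this species, so these signals may not track the organelle transcripts.

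The measured nuclear maturases of mitochondrial introns showed no shift, with a median of −0.10 (camera adjusted p = 0.978) and 0 of 3 members called by limma, adjusted over the list alone or at an unadjusted p under 0.05. NMAT2 was at 0.18 (adjusted p = 0.252), NMAT3 at −0.19 (adjusted p = 0.374) and NMAT4 at −0.10 (adjusted p = 0.513). The remaining member of the list, NMAT1, is not analysed here, since no probe set was named for it.

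The measured cell wall genes showed no list shift. The list for cellulose of primary walls had a median of −0.00, a mean of 0.01 and camera direction down (adjusted p = 0.978), with 0 of 3 members called by limma, adjusted over the list alone or at an unadjusted p under 0.05. Only 3 of its 14 members were measured, and no cellulose synthase gene was among them. COB, for a membrane-anchored protein of cellulose deposition, was at −0.14 (adjusted p = 0.380), and the companion-type genes AT5G42860 and AT1G45688 at 0.18 (adjusted p = 0.574) and −0.00 (adjusted p = 0.990). The expansin and xyloglucan endotransglucosylase list had a median of 0.20 but a mean of −0.01, with camera direction up (adjusted p = 0.969), 2 higher and 1 lower of 7, and 2 higher and 3 lower adjusted over the list alone. XTH18, a xyloglucan endotransglucosylase gene, rose by 1.08 (adjusted p = 0.00293). The expansin gene EXPA15 fell by 0.58 (adjusted p = 0.0193), lost without css1 replicate 1 (adjusted p = 0.113) and css1 replicate 2 (adjusted p = 0.127). XTH16, of the same family as XTH18, rose by 0.36 (adjusted p = 0.0448), lost without each array (adjusted p = 0.0686 to 0.212). The expansin gene EXPA4 was at −0.41 (adjusted p = 0.0546) and passed with the filter, trend or array weights and without wild type replicate 1 (−0.52, adjusted p = 0.0356; 0.0356 to 0.266 over all alternatives). The secondary wall gene GUT2 (−0.29, adjusted p = 0.102) and the lignin genes HCT (−0.22, adjusted p = 0.188) and CCR2 (−0.14, adjusted p = 0.629) did not pass over all probe sets, and GUT2 alone passed adjusted over the list alone.

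Nuclear photosynthesis genes had a median of −0.10 (camera adjusted p = 0.417) and 1 of 8 members lower, also 1 adjusted over the list alone. The list passed without wild type replicate 1 (−0.25, adjusted p = 0.00576), with adjusted p from 0.00576 to 0.949 over all alternatives. LHCB4.3, for a minor antenna protein, fell by 0.60 (adjusted p = 0.0165), lost without css1 replicate 1 (adjusted p = 0.109) and css1 replicate 2 (adjusted p = 0.0850). The Rubisco activase gene RCA (−0.23, adjusted p = 0.128), the photosystem I gene PSAE-1 (0.13, adjusted p = 0.586) and the antenna gene LHCB4.1 (−0.10, adjusted p = 0.611) did not pass.

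Of the jasmonate list, PDF1.2 and THI2.1 were measured, and both rose, also adjusted over the list alone. THI2.1, a thionin gene, rose by 0.47 (adjusted p = 0.0246) from a wild-type signal of 3.51 near the floor of the arrays, and its call was lost without each array (adjusted p = 0.0580 to 0.169). The auxin list did not pass (camera adjusted p = 0.201), with 1 of 5 members higher, also 1 adjusted over the list alone. It passed without wild type replicate 2 (adjusted p = 0.0485), with a range of 0.0485 to 0.758 over all alternatives. GH3.3, for an enzyme that conjugates auxin, rose by 1.79 (SE 0.12, adjusted p = 0.00214). The lateral organ boundary genes LBD29 (0.19, adjusted p = 0.191) and LBD16 (0.24, adjusted p = 0.266) and the auxin response gene IAA29 (−0.21, adjusted p = 0.505) did not pass.

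The cold and drought list had a median of −0.18 and a mean of 0.02 with camera direction down (adjusted p = 0.978), and 1 higher and 1 lower of 3, also adjusted over the list alone. The dehydrin gene COR47 fell by 0.85 (adjusted p = 0.00955), lost without css1 replicate 1 (adjusted p = 0.0710) and css1 replicate 2 (adjusted p = 0.0734). COR15A, for a chloroplast protein induced by cold, rose by 1.08 (adjusted p = 0.0191), lost without wild type replicate 2 (adjusted p = 0.0698) and css1 replicate 2 (adjusted p = 0.0650). Its neighbour COR15B was at −0.18 (adjusted p = 0.865), passing as higher without wild type replicate 1 (0.71, adjusted p = 0.0296) and as lower without wild type replicate 2 (−1.06, adjusted p = 0.0173). The heat shock list had a median of 0.02 and a mean of −0.03 with camera direction down (adjusted p = 0.978), and 0 of 3 members called by limma, adjusted over the list alone or at an unadjusted p under 0.05. Its members were HSA32, a gene of heat acclimation (−0.14, adjusted p = 0.335), and the small heat shock protein genes AT1G53540 (0.04, adjusted p = 0.807) and ATHSP22.0 (0.02, adjusted p = 0.942).

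Markers of other tissues showed no list shift. The root list had a median of −0.33 with camera direction down and fry direction up (camera adjusted p = 0.969), 1 higher of 3, and 1 higher and 2 lower adjusted over the list alone. PYK10, a root glucosidase gene, rose by 0.50 (adjusted p = 0.0199), lost without css1 replicate 1 (adjusted p = 0.132), css1 replicate 2 (adjusted p = 0.101) and wild type replicate 2 (adjusted p = 0.0574). The root hair expansins EXPA18 (−0.51, adjusted p = 0.0858) and EXPA7 (−0.33, adjusted p = 0.123) did not pass. The guard cell list did not pass (camera adjusted p = 0.228), with 1 of 3 lower, also 1 adjusted over the list alone. Of its 3 members, only 1 lay above the filter's 30th percentile of mean signal. The stomatal regulator gene FMA fell by 0.37 (adjusted p = 0.0453), lost without each array (adjusted p = 0.0939 to 0.254), and the stomatal lineage genes MUTE (−0.16, adjusted p = 0.376) and SPCH (−0.13, adjusted p = 0.562) did not pass.

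Lists with fewer than 3 measured members had no other call over all probe sets. The iron regulator gene BHLH101 was at −0.57 (adjusted p = 0.425), the glucosinolate genes UGT74B1 at 0.16 (adjusted p = 0.353) and BCAT4 at 0.19 (adjusted p = 0.455), and the salicylate defence gene SAG101 at −0.08 (adjusted p = 0.607). The cell division kinase genes AUR2 and AUR1 were at 0.31 (adjusted p = 0.0907) and 0.02 (adjusted p = 0.953), and AUR2 alone rose adjusted over the list alone. The pollen marker LAT52 was at 0.07 (adjusted p = 0.764).

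Of the 22 lists tested, 10 passed with camera at the preset correlation, 7 higher and 3 lower, and all 10 passed without each array in turn. The other set test, fry, called 5 of these higher and 1 lower, and camera with an estimated correlation called 0 of them.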

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

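The control probe sets of the arrays were not part of any planned test, and they were examined only after the gene results had been seen. They are given here since they hold signal that no comparison above used. The Bacillus poly-A controls had a median log2 difference of 0.23 between css1 and wild type, with 26 of 27 probe sets higher in css1 and 1 called by limma, that for the 3' end of lys (0.39, adjusted p = 0.0457). Several of these probe sets cover parts of the same spiked transcript, as those for GAPDH cover parts of GAPDH. Their counts are therefore not numbers of independent observations. The 18 hybridization controls had a median of 0.00. Among the Arabidopsis controls, probe sets for GAPDH were higher in css1 by 0.63, 0.65, 0.53, 0.60 and 0.51 (adjusted p = 0.0106 to 0.0191), and the probe set for 25S ribosomal RNA by 0.47 (adjusted p = 0.0449). No explanation of these values was tested. In size, the poly-A median was close to the medians of 3 lists called higher, complex I (0.26), alternative respiration (0.25) and the tricarboxylic acid cycle (0.28). Camera tests a list against all other loci, so an offset shared by all loci would not produce such a call. Relative to the wild-type mean, the poly-A median was −0.105 on wild type 1 and 0.105 on wild type 2. It was 0.168 on css1 1 and 0.246 on css1 2, so the wild-type arrays differed among themselves as well.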

How the results depend on the processing

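No alternative here was chosen after its results were seen. A value set out for a single maturase gene was not run, since no probe set was named for it. The 3559 calls numbered 1816 with 1 probe set per locus (910 higher, 906 lower; fewer probe sets tested), 773 at an adjusted p under 0.01 (435, 338), 569 at 2-fold or more (359, 210) and 0 (0, 0) with the plain two-sample t-test, where 4805 had an unadjusted p under 0.05. With the replicate number as a block they numbered 1264 (629, 635), although these numbers only share a number and the correlation of same-number deviations was −0.006. The calls shared with the 3559 were 3233 of 3566 with centring, 3449 of 3882 with trend, 3559 of 3732 with robust, 3268 of 3913 with the filter, 3445 of 3630 with quantile normalization, 3509 of 3614 with array weights and 1240 of 1264 with the block, all in the same direction. Without each array in turn there were 560 to 3079 calls, 336 to 1586 higher and 224 to 1493 lower (fewer arrays). List members that rose numbered 44, against 20 to 37 without each array, 26 with the block, 57 adjusted over the list alone and 0 with the t-test, and those that fell 26, against 3 to 25, 32 adjusted over the list alone and 0. Of the lists, 7 were higher and 3 lower, 0 and 0 with an estimated correlation, and 5 and 1 with fry. The plastid list, at −0.30, lost its call with an estimated correlation (adjusted p = 0.544) and with fry (adjusted p = 0.276). COR15B, not called at −0.18, ranged from −1.06 without wild type replicate 2 to 0.71 without wild type replicate 1 (adjusted p = 0.0296), reversed. Of 107 named results, the t-test ended 61 calls, the block 12, and leaving out css1 replicate 1, css1 replicate 2, wild type replicate 1 and wild type replicate 2 ended 24, 26, 4 and 7. Since the t-test rests on 2 degrees of freedom, its loss of every named call was nearly fixed by the design. Where no construction is named above, the cause was not tested. In simulated data with 200 changed probe sets, 2.99%, 77.6% and 98.5% of changes of 0.5, 1 and 2 log2 units were recovered, rates that do not carry over to data with more changes.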

Other observations

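The tests of single arrays for the mitochondrial and hypoxia lists and the test of the root share were chosen after the values they use had been seen, and the screen of symbol families was not planned. The other tests below had their predictions written before their values were seen, although after the list results. Further genes of defence hormones moved in opposite directions in css1. Of the further jasmonate and ethylene genes, 4 of 18 were measured and 3 rose: AT4G17470, a thioesterase-type gene (2.53), AT3G51450, a strictosidine synthase-type gene (1.44), and AT2G38240, an oxygenase gene of jasmonate breakdown (1.05). Their median was 1.25 (camera adjusted p = 2.81e-04 over the 4 further lists; adjusted p = 0.210 with an estimated correlation). Of the further salicylate genes, 5 of 25 were measured and 3 fell: AT5G55450, a lipid transfer-type gene (−1.40), AT3G28540, an ATPase gene (−0.79), and RING1, a ubiquitin ligase gene (−0.76). Among 43 families of genes with a shared symbol, 0 passed with camera and 6 had an unadjusted p under 0.05. The prefix PDF, which groups 5 plant defensin genes with the peptide deformylase genes PDF1A and PDF1B, had the smallest p (adjusted p = 0.171), and the defensin genes PDF1.2, PDF1.2b (2.77) and PDF1.4 (1.82) rose.

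The further salicylate genes had a median of −0.76 (camera adjusted p = 0.0172; adjusted p = 0.449 with an estimated correlation), which met the prediction for an opposite shift of salicylate and jasmonate genes. Jasmonate and ethylene signalling may therefore be raised, and salicylate signalling lowered, in css1 seedlings. With 5 and 4 genes measured and no hormone data analysed here, this is a hypothesis. By limma, CYP71B23 (0.12, adjusted p = 0.612) and AT1G13470 (−0.74, adjusted p = 0.113) of the further salicylate genes did not pass. Neither did AT3G11180 of the further jasmonate genes (0.06, adjusted p = 0.855) or SAG101 of the planned salicylate list (−0.08, adjusted p = 0.607). The estimated correlation of the further salicylate genes was 0.77.

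The rise of the mitochondrial dysfunction genes might have come from the expression level of the list's members or from a single array. The list's median stood at percentile 100 of 10000 random lists matched on expression, whose central range was −0.21 to 0.15. The lowest median over the 4 pairs of a css1 and a wild-type array was 1.05. Neither explanation held, and the list lost its call with an estimated correlation (adjusted p = 0.280). That the rise reflects mitochondrial stress in css1 is a hypothesis that was not tested, and mitochondrial function is not analysed here.

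The lower hypoxia genes might reflect a smaller share of root tissue, which the 3 measured root markers cannot decide. Their median of −0.33 lay above that of the hypoxia list by more than their SD of 0.54. However, they disagreed, since PYK10 was higher by 0.50 and the root hair expansins were lower. A single array did not explain the lower hypoxia genes, since the highest median of that list over the array pairs was −0.89. Further hypoxia genes, 15 of 24 measured, had a median of −0.54, with 8 lower (camera adjusted p = 2.81e-04; adjusted p = 0.210 with an estimated correlation), such as the low-oxygen response genes AT5G66985 (−1.29) and AT3G10020 (−0.92), while 4 had higher means without passing, such as the fermentation gene PDC2 (0.41, adjusted p = 0.0561). These values fit a hypothesis of lower low-oxygen signalling in css1. However, another cause that lowered the hypoxia list could lower these further genes too, so the test cannot tell such causes apart. Oxygen was not analysed here, so its part stays open.

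The lower sugar-starvation genes might reflect a higher sugar status in css1, for which a fall of further sugar-repressed genes was predicted. The further sugar-repressed genes, 5 of 19 measured, had a median of 0.0207 with an SD of 0.56 and 1 lower gene, the kelch repeat F-box gene AT1G23390 (−0.90). The predicted fall was not seen (camera adjusted p = 0.868), and the outcome written beforehand against this explanation was met. The median lay within the spread of these few genes, a limit that was not part of the prediction, so sugar status stays open. The expression level of the list's members did not explain the fall, since the median stood at percentile 1.02 of the matched random lists. The sugar-starvation list itself lost its call with an estimated correlation (camera adjusted p = 0.516) and with fry (adjusted p = 0.0663).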
